A study of Rattus norvegicus with 7 samples.

How the data were processed

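RNA of 7 cultures of the rat kidney epithelial line NRK-52E was measured, 1 array per culture. Per the labels' protocols, cells in medium with 10% serum were seeded at 20% confluence and transfected by lipofection with 100 pmol of siRNA per ml of medium, RNA was taken 48 h later, and 5 ug of total RNA was made into biotin-labelled cRNA. The groups are siRNA 3488 (2 arrays), siRNA 2600 (2) and a scrambled siRNA (3), taken from the sample titles.

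The deposited values are intensity values, 1 linear signal in arbitrary units per probe set and array, which the authors made with GCOS 1.4, per the submitters' processing notes. The background, summary and scaling settings and the detection calls are not given in the sources used here. The mean signal of each array with the lowest and highest 2% of probe sets left out was 500.1 to 500.2, so the values were already scaled to a common mean. The 98th percentile still ran from 5336 to 6429. The table holds 31099 probe sets, 57 of them controls. A table of the platform's annotation gave 1 gene symbol for 20826 of the others (14217 symbols), several for 436 and none for 9780; no gene was named from the last 2 kinds. Symbols were looked up by Entrez identifier in a gene table of assembly GRCr8, where 20758 were found and 0 changed. No column of the table was left unused.

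Signals under 1 were set to 1 and log2 was taken, with the array scaling as deposited, since the array medians lay within 1.11-fold of each other. Control probe sets were left out, and the upper 60% of probe sets by mean log2 signal, 18625, were tested. Tests used limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend) with Benjamini-Hochberg adjustment, and a probe set was called at an adjusted p under 0.05. Both siRNAs against the control was a fit of 2 groups, in which differences between the siRNAs stay in the spread. The single-siRNA comparisons and siRNA 3488 against siRNA 2600 came from a fit of 3 groups over all 7 arrays, which share 1 estimate of the spread. A log2 change ± its standard error is given for genes, and signals as mean ± SD.

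Lists of genes were fixed before the data were examined, as were the tests, the rule for named genes and the alternatives unless said otherwise. Of 28 lists, 27 had at least 5 tested genes. They were tested with camera at a preset correlation of 0.01 over 10019 genes, each with its brightest probe set, and adjusted over the 108 tests together. None of the 31 calls held with a correlation estimated per list. A higher correlation alone does not account for this loss. For the ER stress list with both siRNAs the estimate was -0.00611, under the preset 0.01. Its unadjusted camera p still rose from 0.000354 to 0.00918. The test fry asks whether the genes of a set move on balance one way. It kept 19 of the 31 and passed 27 of the 108 in all. The median of a list was set against 10000 random lists matched on signal. A gene of a list rose or fell where its probe set was called.

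Named genes are, for both siRNAs against the control, the 12 largest rises and 12 largest falls among called probe sets with 1 symbol (none starting with LOC or RGD and digits) whose arrays do not overlap between the groups, 1 probe set per gene, and 8 each way for the other comparisons. Where fewer qualified, all were named. Of each list that passed, the 4 members with the lowest p are eligible as examples, and Adamts16 is always given. Where several probe sets measure a gene, the named one is that with the largest change, which favours extreme values.

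The fits were tested on simulated data with the real means and the spreads of the fit of 3 groups. In these data 200 of 18625 probe sets were changed. Those spreads leave out differences between the siRNAs, which stay in the spread of the fit of 2 groups. The recovery given for both siRNAs against the control may therefore be too high. For both siRNAs against the control 58%, 96%, 100% and 98% of 50 probe sets each were recovered at 1.5, 2, 3 and 4-fold. For siRNA 3488 these were 44%, 80%, 100% and 98%, and for siRNA 2600 66%, 78%, 98% and 96%. No recovered change had the wrong sign, and 8 to 10 unchanged probe sets were called. Both of 2 planted lists and 0 of 200 unchanged lists were called. The simulated probe sets varied independently of each other, so this does not test list calls where genes of a list are correlated. Alternatives were quantile normalization, median centring, no filter, the upper 40% of probe sets, an offset of 32 before log2, no intensity trend, 1 probe set per gene, the replicate number as a block, other sets of arrays in the fit and leaving out each array. Cyclic loess, signals under the level of the filter raised to that level, and the shared calls from the arrays of the compared groups alone were added after seeing the data. A search of 3′ untranslated regions for siRNA seed matches was planned and is not analysed here.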

Results

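The data are 7 Affymetrix expression arrays of NRK-52E cells, an epithelial line from rat kidney, taken 48 h after transfection with an siRNA. The series concerns Adamts16, a secreted metalloprotease of the ADAMTS family studied in connection with inherited hypertension. The arrays compare cells given an siRNA against its transcript with cells given a scrambled siRNA. Cultures given siRNA 3488 (sense strand AGAAGTACGTCTCCGGAAA) are on 2 arrays, cultures given siRNA 2600 (CCTATATTTCTGTGCGCAA) are on 2, and cultures given the scrambled control (CCTCCAATGTGCTCGGTAAT) are on 3. Each array holds RNA of an independent culture, per the series design. The median signal per array lay between 126 and 139.6, and the small number of arrays limits the precision of every value. The first principal component held 39.2% of the variance and the second 17.4%. On the first, siRNA 2600 replicate 1 (17.7) lay among the control arrays (11.4 to 20.1). Replicate 2 (-6.72) lay between them and the siRNA 3488 arrays (-22.3 and -37.2). Across probe sets, siRNA 2600 replicate 1 correlated with scrambled control replicates 1 and 2 at r = 0.985 and 0.984. With siRNA 2600 replicate 2 it correlated at 0.980.

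Whether the targeted transcript fell could not be read from these arrays. The 1 probe set annotated to Adamts16, 1385969_at, gave signals of 12.1 and 40.4 with siRNA 3488, 21.4 and 2.42 with siRNA 2600, and 8.68, 7.18 and 18.9 with the control. The means were 26.2 ± 20.0 (SD, n = 2), 11.9 ± 13.4 (n = 2) and 11.6 ± 6.37 (n = 3). On average the signal stood at percentile 15.6 of its array, and its mean log2 signal of 3.55 was below the 6.09 needed to enter the tests of all probe sets. In a fit over all probe sets the log2 change with both siRNAs was 0.25 (95% interval -1.78 to 2.29; limma adjusted p = 0.939). With siRNA 3488 it was 1.06 (95% interval -1.24 to 3.36; limma adjusted p = 0.612), and with siRNA 2600 it was -0.56 (95% interval -2.85 to 1.74; limma adjusted p = 0.903). An exact two-sided permutation test of the 4 siRNA arrays against the 3 control arrays gave p = 0.857, and the smallest p that its 35 splits allow is 0.0571. The intervals include large falls and large rises, so a change was not detectable at this signal.

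The first comparison asked what differed between cells with an Adamts16 siRNA, whichever it was, and the control. Kif20a, a kinesin that acts late in mitosis, rose from a signal of 1097 ± 51.3 (SD, n = 3) to 2098 ± 267 (n = 4), a log2 change of 0.93 ± 0.10 (SE; limma adjusted p = 0.0287). Nuf2 and Spc25, subunits of the Ndc80 complex at the kinetochore, rose by 0.78 and 0.70 on the log2 scale, and Knstrn, another kinetochore and spindle protein, rose by 0.63. The mitotic kinase gene Plk1 rose by 0.69, the kinase gene Melk by 0.56 and Mki67, which encodes the proliferation antigen Ki-67, by 0.61. Cks1b and Cdkn3, whose products bind cyclin-dependent kinases, rose by 0.72 and 0.66, and Fancd2, a gene of DNA crosslink repair, rose by 0.68. Phgdh, which encodes the first enzyme of serine synthesis, rose by 0.65, from 1092 ± 111 (n = 3) to 1709 ± 124 (n = 4), and Scoc rose by 0.63. Only 4 named genes fell. They were Mysm1, a histone H2A deubiquitinase gene (-0.67), the splicing regulator gene Rbm5 (-0.58), Taf1, which encodes the largest subunit of the transcription factor TFIID (-0.52), and the endocytic adaptor gene Eps15 (-0.50). The standard errors of these 16 changes lay between 0.07 and 0.11, and their adjusted p between 0.0287 and 0.0485. Other probe sets of some of them gave other values. Those of Mysm1 (0.03), Rbm5 (-0.08 and -0.64), Eps15 (-0.44 and -0.06) and Taf1 (-0.32) did not pass the test. Nor did those of Cks1b (0.54), Scoc (0.46) and Knstrn (0.63).

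Of 18625 probe sets tested, 27 were called at an adjusted p under 0.05, 19 higher and 8 lower with the siRNAs, and 3310 had an unadjusted p under 0.05. The 4 siRNA arrays lay on one side of all 3 control arrays for 3294 of all probe sets tested (17.7%; chance gives 5.71%), and the 27, selected by p, are among them. The count rose to 50 after quantile normalization, to 66 (62 higher, 4 lower) after median centring, and to 1378 when the mean of the 2 siRNA effects was tested in the fit of 3 groups. It was 0 in limma with no filter (3929 at an unadjusted p under 0.05) or without an intensity trend (2995), and 0 with the replicate number as a block (2107). Leaving out 1 array gave 1304 calls without siRNA 2600 replicate 1, 1 call without siRNA 3488 replicate 2 and 0 without siRNA 3488 replicate 1, siRNA 2600 replicate 2 or any of the 3 control arrays (2007 to 3193 at an unadjusted p under 0.05).

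**Figure D1:**
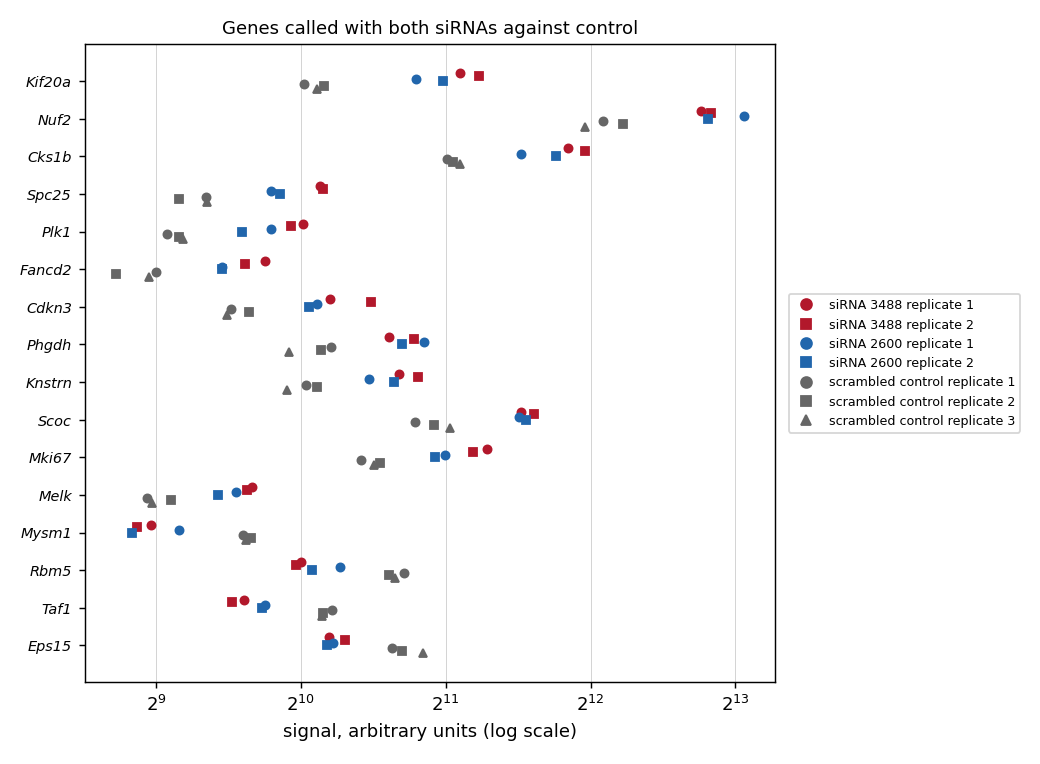
Signal (arbitrary units, log scale) on each of the 7 arrays for the 16 named genes called with both siRNAs against the control; colour and marker give the group and replicate. For Kif20a the 4 siRNA arrays read 1772 to 2403 and the 3 control arrays 1041 to 1142.

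Among the lists of genes fixed beforehand, the cell cycle and DNA replication list stood highest in this comparison. Its 45 tested genes had a median log2 change of 0.41, and 43 of them lay above 0. Kif20a, Plk1, Mki67 and Ccnb1, the gene of cyclin B1 (0.54 ± 0.08), rose, none fell and 41 did not pass. Adjusted over the list alone, 34 rose and 1 fell (camera adjusted p = 1.16e-22, adjusted p = 0.315 with an estimated correlation). The mean over the list was 0.48 and 0.54 above the control mean on the siRNA 3488 arrays and 0.27 and 0.28 above it on the siRNA 2600 arrays, while the control arrays lay between -0.0013 and 0.0024. The ratio of 3′ to 5′ signal of beta-actin, a measure of RNA quality, was likewise higher on all 4 siRNA arrays (1.81 to 1.96) than on the control arrays (1.74 to 1.79), while those of GAPDH and hexokinase overlapped. In the ER stress and unfolded protein response list (34 genes, median 0.11) the 2 genes that rose were Phgdh and Chac1, a glutathione-degrading enzyme gene (0.48 ± 0.07), with 6 adjusted over the list alone (camera adjusted p = 0.00201, adjusted p = 0.224 with an estimated correlation). Neither is a chaperone of the endoplasmic reticulum. Asns, the asparagine synthetase gene, was at 0.50 and did not pass (adjusted p = 0.103).

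Collagens and matrix glycoproteins (31 genes) had a median of 0.19 with 0 called and 5 higher adjusted over the list alone (camera adjusted p = 7.95e-05, adjusted p = 0.315 with an estimated correlation). Elastin (Eln) was at 0.49 and Col1a1 at 0.36, neither passing on its own (adjusted p = 0.0787 and 0.103). The 42 respiratory chain genes had a median of 0.20, with 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 8.67e-10, adjusted p = 0.482 with an estimated correlation). A further 4 lists passed with 0 genes called, and the first 3 with 0 adjusted over the list alone. They include ribosomal proteins (27 genes, median 0.27; camera adjusted p = 4.69e-07, adjusted p = 0.514 with an estimated correlation), mesenchymal and contractile genes (25, 0.14; camera adjusted p = 0.00260, adjusted p = 0.455 with an estimated correlation) and cholesterol and fatty acid synthesis (31, 0.11; camera adjusted p = 0.00279, adjusted p = 0.500 with an estimated correlation). The last was fibroblast markers (8 genes, 0.27, 3 higher adjusted over the list alone; camera adjusted p = 0.0178, adjusted p = 0.315 with an estimated correlation). With siRNA 2600 alone the ribosomal (camera adjusted p = 0.145), mesenchymal (0.187) and fibroblast (0.0629) lists did not pass. With siRNA 3488 alone the cholesterol list did not pass (median 0.04, camera adjusted p = 0.539). Each of these 4 lists therefore passed with only 1 of the siRNAs. Of 14 fibroblast markers on the arrays, 8 passed the signal filter and were tested. Other lists hold 4 of these 8, and the median control signal of the 8 was 1379. Since the filter selects on signal, this does not show how many of the markers these cells express. In this comparison the brightest 10% of probe sets had a median of 0.10, and lists matched to the ribosomal list on signal had a median of 0.23. After quantile normalization the calls of the collagen, mesenchymal, ER stress, ribosomal and fibroblast lists were lost, the last 4 also after cyclic loess. Among lists matched on signal the mesenchymal median stood at percentile 94.7, inside the central 95%. In fry the mesenchymal (adjusted p = 0.111), cholesterol (0.264), respiratory (0.111) and ribosomal (0.264) lists did not pass. The fibroblast call was also lost without siRNA 3488 replicate 1 (adjusted p = 0.0536) or scrambled control replicate 2 (0.0618).

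**Figure D2:**
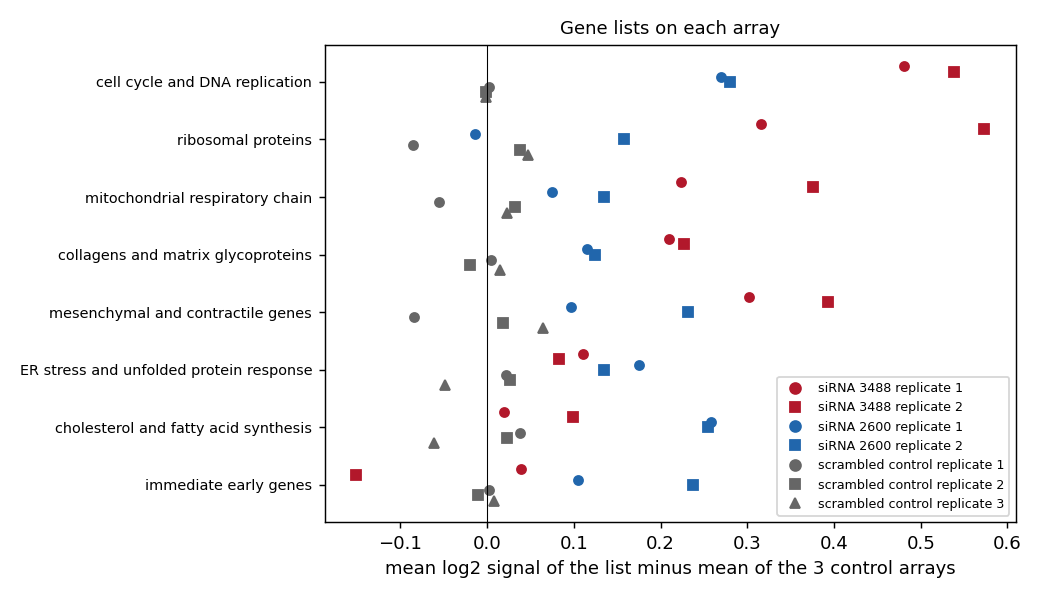
Mean log2 signal of the members of 8 gene lists on each of the 7 arrays, minus the mean of the 3 control arrays; colour and marker give the group and replicate. For the cell cycle list the 4 siRNA arrays lie between 0.27 and 0.54.

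The second comparison set siRNA 3488 alone against the control. Its largest rises were those of Hs6st1, a heparan sulfate sulfotransferase gene, from 394 ± 102 (n = 3) to 2557 ± 90.4 (n = 2), a log2 change of 2.73 ± 0.47 (limma adjusted p = 0.00696), and of Gnb1, which encodes a G protein beta subunit, 2.67 ± 0.59. Poldip3 (2.52), the cardiolipin synthase gene Crls1 (2.40), Rpl7 (2.38), the translation initiation factor gene Eif3h (2.29), calponin 2 (Cnn2, 2.23) and the peroxisomal transporter gene Abcd3 (1.96) followed. The 2 siRNA 2600 arrays differed at these probe sets: Hs6st1 read 300.3 on replicate 1 and 1378 on replicate 2, and Cnn2 read 1087 and 4919. Over the 83 probe sets at least 2-fold higher with siRNA 3488, the mean lay 1.38 and 1.60 above the control mean on the siRNA 3488 arrays, and -0.11 and 1.03 from it on siRNA 2600 replicates 1 and 2. Other probe sets of these genes changed less: 0.05 and 0.33 for Gnb1, 0.47 for Eif3h, 0.47 for Rpl7 and 1.33 for Crls1. The largest falls were those of the transcription factor gene Mef2d, from 223 ± 71.3 (n = 3) to 31.1 ± 4.70 (n = 2), a log2 change of -2.80 ± 0.31 (limma adjusted p = 0.00175), and of Crtc3, a CREB coactivator gene, -2.19 ± 0.39. C10h16orf89 (-2.07), Ier5 (-1.93), the zinc finger gene Mzf1 (-1.86), Dpm1 (-1.85), the glycerol kinase gene Gk (-1.80) and glypican 6 (Gpc6, -1.79) also fell. Apart from Gk (181), these genes had mean signals of 24.5 to 89.8 with siRNA 3488, so near the low end that the sizes of their falls are imprecise. With every signal under a log2 of 6.09 raised to that level, the changes were -1.66 for Mef2d, -1.32 for Dpm1, -1.46 for Gpc6 and -0.76 for Ier5. Those of Mzf1 (-0.88), Crtc3 (-0.80) and C10h16orf89 (-0.58) no longer passed (adjusted p = 0.0761, 0.0551 and 0.180). Other probe sets gave -0.12 for Mef2d, -0.27 for Crtc3, -0.09 for Dpm1, 0.13 for Ier5 and -0.54 for Mzf1, none passing, and -0.68 for Gk, which passed. Those of Gpc6 gave -0.72 and -0.51, which passed, and -0.21, which did not.

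In all, 2911 probe sets were called, 1283 higher and 1628 lower, of which 83 and 111 changed at least 2-fold. The 2 siRNA 3488 arrays lay on one side of the 3 control arrays for 9364 of all probe sets tested (50.3%; chance gives 20%). The count was 1839 after quantile normalization, 591 without an intensity trend and 2304 (1728 higher, 576 lower) after median centring. It fell to 474 without siRNA 3488 replicate 2 and to 980, 1335 and 1748 without scrambled control replicates 1, 2 and 3.

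**Figure D3:**
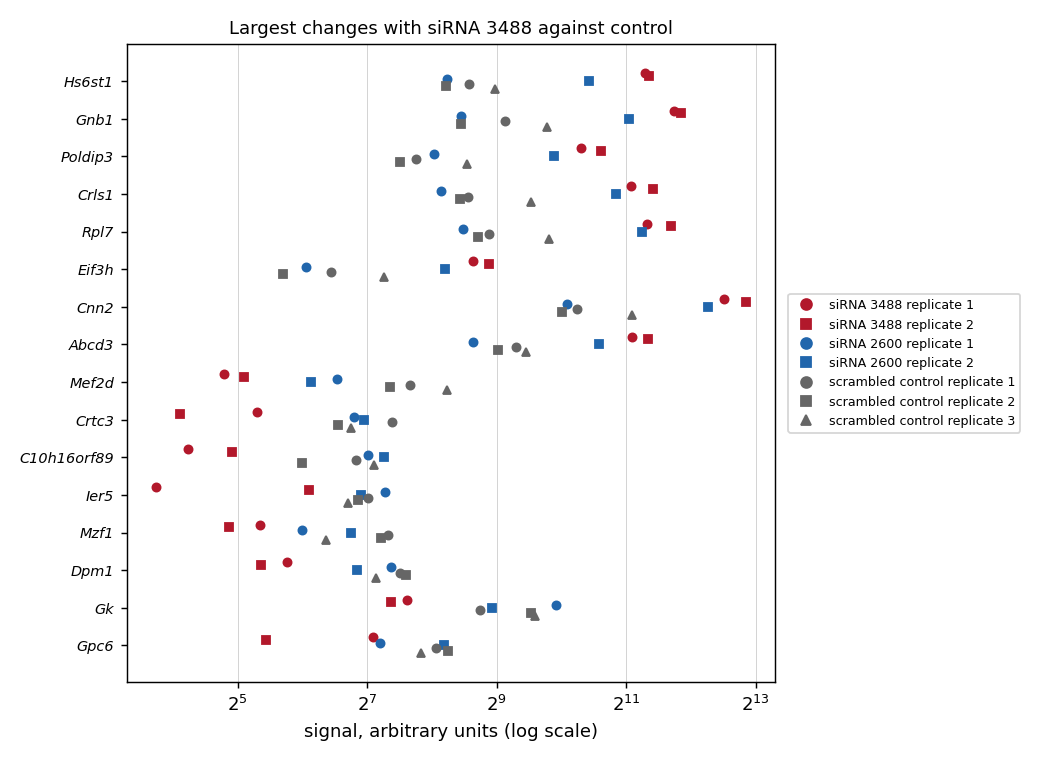
Signal (arbitrary units, log scale) on each of the 7 arrays for the 16 genes with the largest changes between siRNA 3488 and the control; colour and marker give the group and replicate. For Hs6st1 the siRNA 3488 arrays read 2493 and 2620.4, siRNA 2600 replicate 2 read 1378 and siRNA 2600 replicate 1 read 300.3.

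Cell cycle genes rose with siRNA 3488: 34 of 45 were called higher and none lower, with a median of 0.54 (38 higher and 1 lower adjusted over the list alone; camera adjusted p = 3.17e-21, adjusted p = 0.135 with an estimated correlation). Top2a, the topoisomerase gene of dividing cells, rose from 1755 ± 47.5 (n = 3) to 3052 ± 102 (n = 2), a log2 change of 0.80 ± 0.07, and Ccnb2 (cyclin B2) rose by 0.61. Of 27 ribosomal protein genes 26 rose (median 0.46; 26 adjusted over the list alone), among them Rps15 (0.63) and Rpl18 (0.54) (camera adjusted p = 9.15e-16, adjusted p = 0.455 with an estimated correlation). Of 42 respiratory chain genes 27 rose (median 0.31; 30 adjusted over the list alone), with Cox6a1, a cytochrome c oxidase subunit, at 0.64 and Ndufa4 at 0.58 (camera adjusted p = 2.22e-13, adjusted p = 0.455 with an estimated correlation). Of 31 matrix genes 13 rose and 1 fell (median 0.26; 15 and 1 adjusted over the list alone), with Eln at 0.63 ± 0.06 and fibronectin (Fn1) at 0.49 (camera adjusted p = 8.92e-06, adjusted p = 0.224 with an estimated correlation). Of 25 mesenchymal and contractile genes 9 rose (median 0.22; 10 adjusted over the list alone), including the tropomyosin genes Tpm2 (0.54) and Tpm1 (0.44) and vimentin (Vim, 0.45) (camera adjusted p = 6.48e-05, adjusted p = 0.298 with an estimated correlation).

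Of 34 genes of the ER stress list 11 rose and 2 fell with siRNA 3488 (median 0.09; 13 and 3 adjusted over the list alone), including Sec61b, a subunit of the protein translocation channel, at 0.43, and the transcription factor gene Atf4 at 0.43 (camera adjusted p = 0.0234, adjusted p = 0.455 with an estimated correlation). Of 28 hypoxia and glycolysis genes 8 rose and 1 fell (median 0.14; 9 and 4 adjusted over the list alone), with the glycolytic genes Pgk1 at 0.53 and Ldha at 0.40 (camera adjusted p = 0.0493, adjusted p = 0.359 with an estimated correlation). Of 26 lysosome and autophagy genes 6 rose and 1 fell, the same numbers adjusted over the list alone (median 0.08), with Npc2, a carrier of cholesterol in the lysosome, at 0.50 and the autophagy gene Wipi1 at -0.49 (camera adjusted p = 0.0497, adjusted p = 0.455 with an estimated correlation). Of 8 fibroblast markers 3 rose, Col3a1 (0.44), Mfap5 (0.48) and Col1a1 (0.44), with 3 adjusted over the list alone (median 0.32; camera adjusted p = 0.0234, adjusted p = 0.432 with an estimated correlation). Among lists matched on signal the lysosome median stood at percentile 27.2, below the 0.12 of those lists. Inside the central 95% were also the medians of the ER stress (80.2), hypoxia (88.0), fibroblast (95.8) and mesenchymal (96.4) lists. In fry the ribosomal and lysosome lists did not pass (adjusted p = 0.0538 for each). The calls of the ribosomal, matrix, mesenchymal, ER stress, hypoxia, lysosome and fibroblast lists were lost after quantile normalization, where the ribosomal median was 0.00337. The last 4 were also lost after cyclic loess. Directions turned as well: after quantile normalization Col3a1 was at -0.0258 and the lysosome median at -0.0133, and after cyclic loess that median was -0.000290. Leaving out 1 array ended the call of the ER stress list (siRNA 3488 replicate 1, 0.0939; scrambled control replicate 3, 0.0800) and of the fibroblast list (siRNA 3488 replicate 1, 0.104; scrambled control replicate 2, 0.0554). For 5 of the 7 arrays each it ended the call of the hypoxia list (highest adjusted p 0.0744) and the lysosome list (highest 0.108).

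Changes with siRNA 3488 varied with signal. The brightest 10% of probe sets had a median log2 change of 0.15 with siRNA 3488 and 0.05 with siRNA 2600, and lists matched to the ribosomal list on signal had a median of 0.42 with siRNA 3488. The 18 probe sets of the bacterial and phage transcripts added at hybridisation had a median of 0.52 with siRNA 3488 and 0.03 with siRNA 2600. The ratio of 3′ to 5′ signal of beta-actin was 1.96 and 1.94 on the siRNA 3488 arrays, 1.83 and 1.81 on the siRNA 2600 arrays and 1.74 to 1.79 on the control arrays. The ratio of hexokinase was 4.71 and 3.73, 3.54 and 2.28, and 2.39 to 2.98, and that of GAPDH was 0.941 and 0.929, 1.04 and 0.929, and 0.908 to 0.948.

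**Figure D4:**
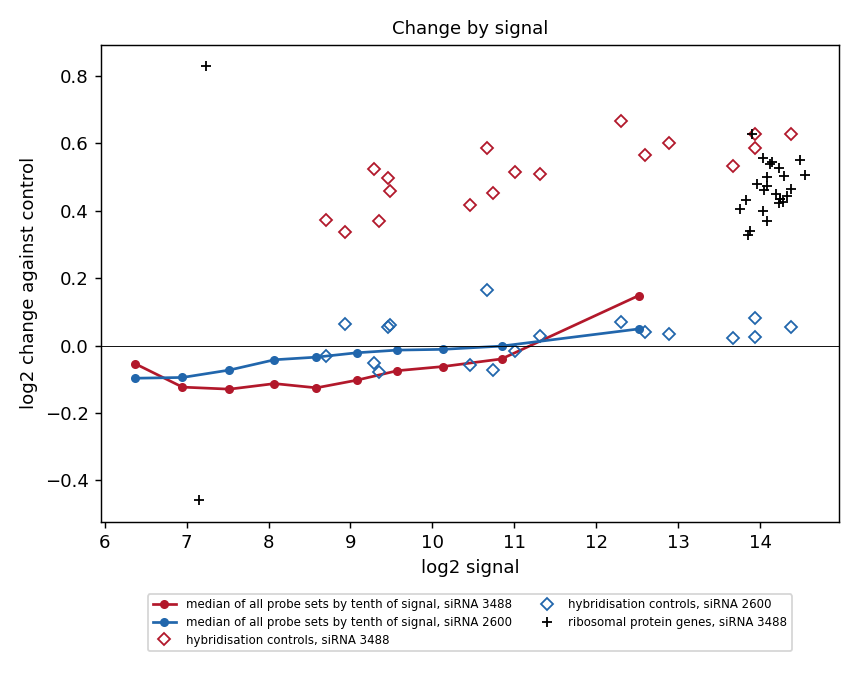
Log2 change against the control plotted against log2 signal, as medians of 10 equal bins of the tested probe sets (lines), for each hybridisation control probe set (diamonds) and for each ribosomal protein gene with siRNA 3488 (crosses). The brightest 10% had a median of 0.15 with siRNA 3488, and the hybridisation controls lay between 0.34 and 0.67.

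The third comparison set siRNA 2600 against the control. Igfbp5, which encodes a binding protein of insulin-like growth factors, rose from 74.1 ± 11.6 (n = 3) to 218 ± 33.0 (n = 2), a log2 change of 1.56 ± 0.26 (limma adjusted p = 0.0246), and its other probe set rose by 0.99. Rgs5, a regulator of G protein signalling, rose by 1.52, the myosin gene Myo1f by 1.34, Mlec, a lectin of the endoplasmic reticulum, by 1.17 and Inhba, the activin A subunit, by 1.06. Lypd8 (0.97), Pafah1b2 (0.94) and Idi1, an enzyme gene of cholesterol synthesis (0.85), also rose, with another probe set of Idi1 at -0.15 (adjusted p = 0.719). The largest fall was that of Amhr2, the anti-Müllerian hormone receptor gene, from 117 ± 20.7 (n = 3) to 34.0 ± 11.1 (n = 2), a log2 change of -1.81 ± 0.30 (limma adjusted p = 0.0258), and -0.76 (adjusted p = 0.120) with signals raised to the level above. Apex2, a DNA repair endonuclease gene (-1.10), extracellular superoxide dismutase (Sod3, -1.08), the transcription factor gene Hlf (-1.04), Tbl1xr1 (-1.02), lipopolysaccharide binding protein (Lbp, -0.93), the Golgi SNARE gene Gosr2 (-0.92) and Usp6nl (-0.87) fell. Other probe sets of Mlec (1.05), Pafah1b2 (0.58) and Gosr2 (-0.51) passed, and those of Inhba (0.60), Hlf (-0.68 and -0.51) and a further one of Pafah1b2 (0.17) did not. Other probe sets of Usp6nl gave 0.29 and 0.11 and those of Tbl1xr1 lay between -0.34 and 0.02, none passing. In all, 192 probe sets were called, 102 higher and 90 lower, of which 8 and 13 changed at least 2-fold. The 2 arrays lay on one side of the control arrays for 6334 of all probe sets tested (34.0%; chance gives 20%). The count was 91 with no filter, 0 in limma without an intensity trend (2585 at an unadjusted p under 0.05) and 205 (160 higher, 45 lower) after median centring. With the replicate number as a block it was 67. It was 96 without siRNA 2600 replicate 2 and 37, 25 and 33 without scrambled control replicates 1, 2 and 3.

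With siRNA 2600 the cell cycle list again had the highest median of the lists that passed, 0.31, with 7 of 45 genes higher, none lower and 27 higher and 1 lower adjusted over the list alone (camera adjusted p = 3.14e-15, adjusted p = 0.135 with an estimated correlation). Kif20a rose by 0.79 ± 0.08 and Mki67 by 0.47. Genes of cholesterol and fatty acid synthesis had a median of 0.21, with Dhcr7 (0.72), Idi1 (0.85) and Sqle (0.56), all enzymes of cholesterol synthesis, higher among 31 and 11 adjusted over the list alone (camera adjusted p = 3.54e-08, adjusted p = 0.315 with an estimated correlation). In the ER stress list (median 0.09) 4 of 34 rose and 10 did adjusted over the list alone (camera adjusted p = 0.000164, adjusted p = 0.315 with an estimated correlation). They were Psat1 (0.70) and Phgdh (0.69), both of serine synthesis, Chac1 (0.48) and Ddit3, the stress transcription factor CHOP (0.51). Of 28 immediate early genes, rapidly induced regulators, Ier2 rose (0.57) and 8 did adjusted over the list alone, with a median of 0.20 (camera adjusted p = 0.000435, adjusted p = 0.455 with an estimated correlation). Of 31 matrix genes Eln (0.35), Fbln5 (0.51) and osteopontin (Spp1, 0.44) rose (6 higher and 1 lower adjusted over the list alone; median 0.07; camera adjusted p = 0.00279, adjusted p = 0.315 with an estimated correlation). The respiratory chain list passed with a median of 0.10 although its 1 called gene, Ndufa5, fell by 0.55, with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 9.10e-05, adjusted p = 0.583 with an estimated correlation). The matrix median stood at percentile 93.1 of lists matched on signal, and in fry the respiratory (adjusted p = 0.271) and immediate early (0.111) lists did not pass. The matrix call was lost after quantile normalization (adjusted p = 0.111) and cyclic loess (0.123).

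The fourth comparison tested the difference between the 2 siRNAs. Igfbp5 was lower with siRNA 3488 than with siRNA 2600 by a log2 change of -1.80 ± 0.28 (limma adjusted p = 0.0121; other probe set -1.39), and Mfap4, a microfibril protein gene, was higher, at 939 ± 88.6 against 421 ± 77.8 (n = 2 each; 1.17 ± 0.15). The cardiac myosin binding protein gene Mybpc3 (3.03), Gsg1 (1.86), Amhr2 (1.82), Rasgrf1 (1.68), Shank1 (1.49), Sult2a2 (1.21) and Trim63 (1.20) were also higher. The mean signals of these 7 lay between 23.8 and 192 in the 2 groups. C10h16orf89 (-2.57), Crtc3 (-2.17), Gk (-1.93), Dedd (-1.61), Dpm1 (-1.55), Giot1 (-1.52) and the glucose transporter gene Slc2a4 (-1.42) were lower. With low signals raised as above, the differences of Mybpc3 (1.48), Gsg1 (1.05), Shank1 (1.22), Trim63 (1.13) and Dpm1 (-1.01) passed. Those of Amhr2 (0.78), Rasgrf1 (0.92), Sult2a2 (0.75), C10h16orf89 (-1.05), Crtc3 (-0.78), Dedd (-0.82) and Slc2a4 (-0.44) did not. Other probe sets gave 0.12 for Dedd, -0.12 for Dpm1, -0.28 for Crtc3, -0.33 for Gk, -0.36 for Slc2a4 and 0.53 for Gsg1, none passing. Cholesterol synthesis genes were lower with siRNA 3488 than with siRNA 2600 (median -0.22; 7 of 31 lower and 1 higher, 11 and 2 adjusted over the list alone; camera adjusted p = 0.00158, adjusted p = 0.455 with an estimated correlation), with Acat2 at -0.61 and Cyp51 at -0.54, although the regulator Srebf2 was at 1.17. The siRNA 2600 arrays differed for Srebf2 (609 and 1270.1), and without replicate 1 its difference was 0.64 and did not pass (adjusted p = 0.0546). Immediate early genes were lower (median -0.28; 7 of 28 lower and 1 higher, 9 and 1 adjusted over the list alone; camera adjusted p = 0.00440, adjusted p = 0.487 with an estimated correlation), with Nr4a1 at -0.91 and Ier2 at -0.78. Cell cycle genes were higher with siRNA 3488 (median 0.20; 8 of 45, 18 adjusted over the list alone; camera adjusted p = 3.80e-09, adjusted p = 0.224 with an estimated correlation), with E2f1 at 1.04 and Tk1 at 0.51.

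Ribosomal protein genes were also higher with siRNA 3488 than with siRNA 2600 (median 0.41; 21 of 27, 26 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.19e-15, adjusted p = 0.455 with an estimated correlation), with Rps16 at 0.46. Respiratory chain genes were higher (median 0.22; 7 of 42, 25 higher and 2 lower adjusted over the list alone; camera adjusted p = 3.80e-09, adjusted p = 0.487 with an estimated correlation), with Cox6a1 at 0.45. Of 31 matrix genes 7 were higher, such as Sparc (0.41), and 2 lower, such as Col12a1 (-0.44), with a median of 0.17 (13 and 3 adjusted over the list alone; camera adjusted p = 0.00594, adjusted p = 0.315 with an estimated correlation). Of 25 mesenchymal and contractile genes 3 were higher, Ccn2, Tpm2 and Tpm1, and Inhba was lower (-0.81), with a median of 0.14 (6 and 1 adjusted over the list alone; camera adjusted p = 0.00261, adjusted p = 0.315 with an estimated correlation). The lysosome list had a median of 0.05 with 3 of 26 higher, Gabarapl1, Ctsl and Lamp2 (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0234, adjusted p = 0.455 with an estimated correlation). Lists matched to the ribosomal list on signal had a median of 0.36, most of its 0.41. The lysosome median lay below the 0.08 of its matched lists (percentile 27.0), and the matrix (93.8) and mesenchymal (83.9) medians lay inside the central 95% too. In fry the immediate early (adjusted p = 0.0880), ribosomal (0.0880), respiratory (0.104) and lysosome (0.0733) lists did not pass. The ribosomal, matrix, mesenchymal and lysosome calls were lost after quantile normalization and the last 3 also after cyclic loess. The test of the lysosome list turned downward after quantile normalization (median 0.00213). The immediate early call was lost without siRNA 2600 replicate 2 (adjusted p = 0.135) and the lysosome call without siRNA 2600 replicate 1 (0.0924). Between the siRNAs 1119 probe sets were called, 529 higher and 590 lower with siRNA 3488. The arrays of the 2 groups did not overlap for 9231 of all probe sets tested (49.6%; chance gives 33.3%). The count was 574, 727 and 694 after quantile normalization, median centring and cyclic loess, 459 with no filter, 5 without an intensity trend and 29 from the 4 arrays compared alone. It was 95 without siRNA 3488 replicate 2, 107 without siRNA 2600 replicate 1 and 444, 367 and 517 without scrambled control replicates 1, 2 and 3.

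Against the control, 75 probe sets were called in the same direction with both siRNAs, 47 higher and 28 lower, and 4 in opposite directions. They make up 39.1% of the siRNA 2600 calls, 7 of them belong to genes of the cell cycle list, and they include all 27 probe sets called in the first comparison. In 100 simulations of unchanged groups sharing the 3 control arrays the mean count was 0.0400, and independent lists of these sizes would share 14.9 (7.03 higher, 7.87 lower). With nothing changed, the adjustment lets almost no probe set pass in either comparison. A very low simulated count was therefore set in advance and is no measure for the 75. The simulations drew each probe set independently, without a component common to all probe sets of an array. They therefore cannot show how many shared calls a structure common to some arrays would give. Across probe sets, which are not independent replicates, the log2 changes with the 2 siRNAs correlated with r = 0.431 against 0.400 in the simulations, 66.6% against 63.1% had the same sign, and the covariance was 0.0370 against 0.0133. The 3 control arrays cannot be split into 2 parts of at least 2 arrays, so part of the excess may come from the shared control. The count was 35 with no filter and 0 without an intensity trend, where limma called 591 with siRNA 3488 and 0 with siRNA 2600. It was 25 with the replicate number as a block. Without 1 array it was 147 (siRNA 2600 replicate 1), 33 (siRNA 3488 replicate 2 or siRNA 2600 replicate 2), and 8, 7 and 8 (scrambled control replicates 1, 2 and 3).

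**Figure D5:**
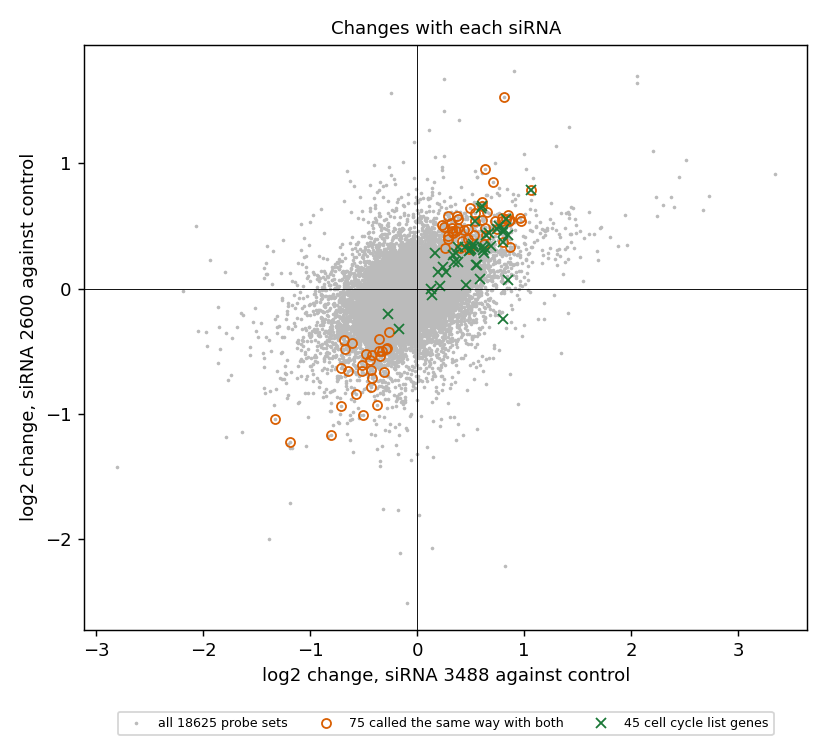
Log2 change against the control with siRNA 3488 (horizontal) and siRNA 2600 (vertical) for all 18625 tested probe sets (grey), with the 75 called in the same direction with both siRNAs (open circles) and the 45 genes of the cell cycle list (crosses). The cell cycle genes had medians of 0.54 and 0.31.

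The other lists, 16 in all, passed camera in none of the 4 comparisons. The ADAMTS family (9 genes tested) had a lowest camera adjusted p of 0.385 (between the siRNAs, median 0.01), with 1 member lower with siRNA 2600. The lowest adjusted p over the 4 comparisons was 0.145 for matrix proteases and their inhibitors, 0.147 for integrins and focal adhesion, 0.145 for the primary cilium and 0.0654 for epithelial junctions and keratins. For kidney functions it was 0.234 for the proximal tubule, 0.711 for sodium and potassium transport and 0.304 for vasoactive and renin-angiotensin genes. Among responses to foreign RNA and stress it was 0.205 for the interferon response, 0.160 for NF-kB and inflammatory genes, 0.530 for p53 targets, 0.200 for NRF2 and glutathione, 0.385 for the small RNA machinery and 0.304 for heat shock proteins. Markers of leukocytes (0.313, 5 genes) and of podocytes and smooth muscle (0.399, 6 genes) did not pass either, and endothelial markers had 3 tested genes, too few for the test. In fry 5 of these lists did pass. NF-kB genes (medians -0.11 and -0.20; adjusted p = 0.0102 for each) and the primary cilium (-0.14 and -0.12; 0.0479 and 0.0423) were lower with siRNA 3488 than with the control and with siRNA 2600. Between the siRNAs the interferon response (-0.08; 0.0262, 4 members lower) and vasoactive genes (-0.17; 0.0423) were lower with siRNA 3488, and epithelial junctions (0.19; 0.0491) were higher, with 1 member lower. The last test that fry alone passed was hypoxia and glycolysis with both siRNAs (0.11; 0.0440). Among lists matched on signal these medians lay inside the central 95%, apart from NF-kB genes between the siRNAs (percentile 0.91). The others stood at 15.5 (NF-kB), 6.32 and 6.17 (cilium), 23.0 (interferon), 3.41 (vasoactive), 94.5 (epithelial) and 93.5 (hypoxia). With siRNA 3488 against the control 3 NF-kB and 4 cilium genes were called lower and 1 of each higher. Between the siRNAs 3 NF-kB, 0 cilium and 0 vasoactive genes were called. In 11 of the 108 list tests the median, the mean and the direction of the test were not all of the same sign, none of them among the 31 that passed.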

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

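The tests of signal response for the ribosomal and respiratory lists, of RNA degradation, of the Adamts16 level, of other probe sets of the same genes and of a mixed array, and the raising of low signals, were chosen after the results were seen; the other tests in this part were fixed before their own result was seen. The bounds for the signal response of both lists and for RNA degradation in them were rewritten after the results. Under the bounds first written, the signal response of the ribosomal list and RNA degradation would both have been argued against. The test of other probe sets was later redone to include those that are themselves among the largest rises. That moved its outcome from favouring a signal of single probe sets to undecided. A mislabelled and a mixed array were first a single explanation and were separated later.

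The siRNAs differed from each other at 1119 probe sets in a test of the difference itself. Higher with siRNA 3488 than with siRNA 2600 on the log2 scale were Mybpc3 (3.03), Gsg1 (1.86), Amhr2 (1.82), Rasgrf1 (1.68), Shank1 (1.49), Sult2a2 (1.21), Trim63 (1.20) and Mfap4 (1.17), and lower were C10h16orf89 (-2.57), Crtc3 (-2.17), Gk (-1.93), Igfbp5 (-1.80), Dedd (-1.61), Dpm1 (-1.55), Giot1 (-1.52) and Slc2a4 (-1.42). Signals near the low end make several of these sizes imprecise: with low signals raised to a log2 of 6.09, Mybpc3 was at 1.48 and Gsg1 at 1.05, and Amhr2 (0.78), Rasgrf1, Sult2a2, C10h16orf89, Crtc3, Dedd and Slc2a4 no longer passed. The lists that differed were collagens and matrix glycoproteins (median 0.17), mesenchymal and contractile genes (0.14), cell cycle (0.20), cholesterol and fatty acid synthesis (-0.22), respiratory chain (0.22), ribosomal proteins (0.41), immediate early genes (-0.28) and lysosome and autophagy (0.0535), none of which passed with an estimated correlation (adjusted p = 0.224 to 0.487). Their lowest-p members that differed were, for the matrix, Col12a1 (-0.44), Sparc (0.41), Fn1 (0.39) and Lox (0.38), though Lox turned to -0.0095 after quantile normalization (adjusted p = 0.923). For mesenchymal genes they were Ccn2 (0.47), Tpm2 (0.46), Inhba (-0.81) and Tpm1 (0.42), for the cell cycle Tk1 (0.51), Top2a (0.43), E2f1 (1.04) and Ccnb2 (0.31), and for cholesterol synthesis Acat2 (-0.61), Acss2 (-0.52), Srebf2 (1.17) and Cyp51 (-0.54). Srebf2 read 609 and 1270.1 on the siRNA 2600 arrays, and without replicate 1 its difference was 0.64 and did not pass. For the respiratory chain they were Cox6a1 (0.45), Cyc1 (0.33), Atp5pb (0.37) and Cox6c (0.43), for ribosomal proteins Rps16 (0.46), Rps29 (0.44), Rpl14 (0.40) and Rpl22 (0.46), for immediate early genes Junb (-0.50), Ier2 (-0.78), Nr4a1 (-0.91) and Egr2 (-0.76), and for the lysosome Gabarapl1 (0.39), Ctsl (0.39) and Lamp2 (0.43).

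Probe sets of transcripts added at hybridisation, which no comparison uses, stood apart on the siRNA 3488 arrays. The 18 probe sets had a median log2 change of 0.52 against the control (1.43-fold; 0.34 to 0.67), and 17 of them lay above every control array on both siRNA 3488 arrays. Their mean was 0.33 and 0.70 above the control mean on these arrays and -0.09 and 0.13 from it on the siRNA 2600 arrays. Scan dates and hybridisation batches are not given in the sources used here, so a batch that coincides with siRNA 3488 was not tested for the 2911 calls of that comparison. Transcripts added before labelling (24 probe sets) had medians of -0.20 and 0.03.

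Ribosomal protein and respiratory chain genes were higher with siRNA 3488, with medians of 0.46 and 0.31. An array response that grows with signal was tested against 10000 lists matched on signal: the respiratory list lay above all of them (percentile 100), and its excess of 0.13 and 0.21 on the siRNA 3488 arrays exceeded the -0.04 to 0.03 of the control arrays, which argues against that response as the whole cause. The percentile alone does not decide, since the list stood at 0.04 and 99.9 on scrambled control replicates 1 and 2. The argument rests on the size of the excess, on 2 arrays against 3. The ribosomal list stood at percentile 99.2, but matched lists rose by 0.42 of its 0.46, and it stood at percentile 92.4 on siRNA 3488 replicate 1 and 99.6 on scrambled control replicate 3, so the array response and a change of these genes cannot be told apart. RNA degradation with 3′ bias stays open for both lists, since 2 of 3 transcripts had a higher 3′ to 5′ ratio on both siRNA 3488 arrays than on every control array. An effect of siRNA 3488 in the cells, through Adamts16 or another transcript, remains an untested hypothesis.

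Cell cycle genes were higher with both siRNAs, with medians of 0.54 and 0.31. A response that grows with signal is argued against by the percentile of the list among lists matched on signal, 100 in each single-siRNA comparison, and a single aberrant siRNA array by the gap of 0.27 between the lowest siRNA array and the highest control array. RNA degradation with 3′ bias stays open, since the 3′ to 5′ ratio of 1 of 3 transcripts, beta-actin, was higher on all 4 siRNA arrays than on every control array, in the order of the list (siRNA 3488, siRNA 2600, control). Those of GAPDH and hexokinase overlapped between the groups. Hexokinase on siRNA 2600 replicate 2 (2.28) lay below every control array (2.39 to 2.98). Slower growth of the control cultures cannot be told apart from faster growth with the siRNAs, since 0 of the arrays hold untransfected cells, and loss of the Adamts16 transcript cannot be judged, since its signal stood at percentile 15.6 of the array on average. That an Adamts16 siRNA raised cell cycle transcripts relative to the control is a hypothesis that may hold, and these tests do not bear on its mechanism.

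The largest rises with siRNA 3488 were also seen on siRNA 2600 replicate 2 and not on replicate 1: of the 83 probe sets at least 2-fold higher, replicate 2 lay nearer to the siRNA 3488 mean than to the control mean for 68 and replicate 1 for 5, with 65 for replicate 2 alone. Over the 83 the array means were 1.38, 1.60, -0.11, 1.03 and, for scrambled control replicate 3, 0.28 from the control mean, and of the 111 lower ones replicate 2 lay nearer for 45 and replicate 1 for 15. A wrong label of siRNA 2600 replicate 2, which would make it an siRNA 3488 array, is argued against by the 96 probe sets called from replicate 1, where replicate 2 moved 3.13 times as far in the same direction as siRNA 3488 did (medians 0.52 and 0.17; same direction for 89 of 96). A part mixture with siRNA 3488 RNA cannot be told apart from an unmixed array, since replicate 2 stood at 0.649 of the distance from siRNA 3488 to replicate 1 (median 0.71, raised by the selection on that array). A signal of single probe sets or transcript forms, technical or biological, stays open too: the other probe sets of the same genes (36 probe sets of 23 genes, with 5 of these probe sets also among the 83) had a median of 0.32 against 1.32, which is 24.7% (95% interval 7.41% to 57.1%).

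Chance could not be excluded for the 27 calls with both siRNAs: 3 of the 35 splits of the 7 arrays into 4 and 3, the real grouping among them, called at least as many. The highest other count was 1256, from setting siRNA 2600 replicate 1 and the 3 control arrays against the other arrays, and a further split, of siRNA 2600 replicate 2, scrambled control replicate 3 and the siRNA 3488 arrays against the rest, called 118. A split that calls so many points to a structure of the arrays beyond their groups.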

How the results depend on the processing

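Cyclic loess, the raising of signals under a log2 of 6.09 to that level, and shared calls from the compared arrays alone (77) were chosen after seeing the data; the other alternatives were planned. The counts were 27 (both siRNAs), 2911 (siRNA 3488), 192 (siRNA 2600), 1119 (between the siRNAs) and 75 (called with both in the same direction). Counts not given below stayed within 1.5 times of these. Quantile normalization gave 50 for both siRNAs, 1839 for siRNA 3488 and 574 between the siRNAs, and median centring gave 66 for both siRNAs and 727 between the siRNAs. Median centring moved the share of higher calls from 19 of 27 to 62 of 66, from 1283 of 2911 to 1728 of 2304, from 102 of 192 to 160 of 205 and, of those called with both, from 47 of 75 to 83 of 89. Raising low signals gave 30, 2968, 230, 1159 and 93 in that order; of 182 results for named genes it ended 11 calls and added 1. Cyclic loess gave 694 between the siRNAs, and siRNA 3488 and siRNA 2600 had 1949 and 214 calls there. With no filter, which tests more probe sets, the counts were 0 for both siRNAs, 91 for siRNA 2600, 459 between the siRNAs and 35 called with both. Without an intensity trend they were, in the order above, 0, 591, 0, 5 and 0 (2995 and 2585 at an unadjusted p under 0.05 in limma for both siRNAs and siRNA 2600). The mean of the 2 siRNA effects in the 3-group fit gave 1378, and the 4 arrays compared alone gave 29 between the siRNAs; fewer arrays leave fewer degrees of freedom. For the others the cause was not tested.

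Leaving out an siRNA array leaves its group with 1 array, which is assumed to vary like the other groups. Without 1 array the counts ranged, in the order above, from 0 to 1304, 474 to 3611, 25 to 231, 95 to 1562 and 7 to 147, and the log2 change of Adamts16 from -0.31 to 1.05, negative without siRNA 3488 replicate 2, siRNA 2600 replicate 1 or scrambled control replicate 2. Of 182 results for named genes, leaving out 1 array kept side and direction 856 times, ended a call 401 times, added one 17 times and turned the direction 0 times.

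Whether the replicate numbers pair the arrays could not be decided. Deviations from the group means of arrays with the same number correlated at 0.14, 0.14, 0.07, 0.16, 0.02 and -0.05. The values of 0.14 are equal by construction, since the deviations within each siRNA group are equal and opposite. Deviations of arrays with different numbers were not compared, so these values neither show nor exclude a pairing. With the replicate number as a block, limma called 0 for both siRNAs (2107 at an unadjusted p under 0.05), 2721 with siRNA 3488, 67 with siRNA 2600, 1561 between the siRNAs and 25 with both in the same direction, and 34 list tests passed.

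Of 108 list tests 31 passed, 0 with an estimated correlation, 27 with fry (19 of the 31 and 8 others), 14 after quantile normalization, 19 after cyclic loess and 27 to 33 without 1 array. Directions reversed for the lysosome list with siRNA 3488 (-0.0133 after quantile normalization, -0.000290 after cyclic loess) and, by its test, between the siRNAs (0.00213 after quantile normalization). The ER stress median with siRNA 3488 was -0.01 there, with the test still upward. Quantile normalization also reversed Ccn2 (-0.0428) and Col3a1 (-0.0258) with siRNA 3488, and Lox (-0.0095) and Npc2 (-0.0205) between the siRNAs. Their mean log2 signals lie between 13.44 and 14.38. The cause was not tested. Signal limits the result for Adamts16, whose probe set lies near the floor.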

Other observations

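Families of genes that share the letters of their symbol (107 with at least 10 tested genes) were tested in the 4 comparisons after the data had been seen, and 34 of the 428 tests passed. None did with an estimated correlation (adjusted p = 0.797). The Mcm family (10 genes), which holds the helicase that opens DNA at replication, had medians of 0.33 with both siRNAs, 0.47 with siRNA 3488 and 0.21 with siRNA 2600 (camera adjusted p = 0.00134, 0.00548 and 0.0168), with 6 members higher with siRNA 3488; most of them are also in the cell cycle list. Large mitochondrial ribosomal proteins (Mrpl, 46 genes) had medians of 0.13, 0.14 and 0.11 (0.000257, 0.00725 and 0.00129), with 9 higher and 1 lower with siRNA 3488. With both siRNAs the kinesin family (Kif, 22 genes) had a median of 0.16 (0.0414) and the Lsm family, which binds small nuclear and decaying RNAs, one of 0.19 (0.0278). The Rgs family of regulators of G protein signalling (10 genes) had a median of 0.36 with siRNA 2600 (0.0240), with Rgs5 higher.

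With siRNA 3488, Zbtb zinc finger genes (34) had a median of -0.25, with 10 lower and 0 higher (adjusted p = 0.00899), and of -0.24 against siRNA 2600 (0.00735). Zfp zinc finger genes (187) had a median of -0.13 with 22 lower and 5 higher (0.0265), histone demethylase genes (Kdm, 14) one of -0.24 with 4 lower (0.0373) and myotubularin phosphatase genes (Mtmr, 10) one of -0.22 with 3 lower (0.0373). Of all 18625 probe sets tested, 1628 were lower and 1283 higher with siRNA 3488. With probe sets binned by signal into 10 equal bins from dim to bright, bins 2 to 6 had medians of -0.10 to -0.13. The Zfp median was of that size. After quantile normalization, median centring and cyclic loess the medians of all families named above kept their sign, those of Zfp at -0.06, -0.04 and -0.05. Of all family results that passed, 3 turned sign, each after quantile normalization. They belong to the ribosomal protein families Rpl and Rps, where the medians came near 0. Calls of the families under these scalings were not tested.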
